A study of Mus musculus with 9 samples.

How the data were processed

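CD4+ T cells of C57BL/6 mice carrying a reporter of T-bet expression (the fluorescent protein ZsGreen) were cultured under Th1 conditions with irradiated, T-cell-depleted splenocytes, per the labels' protocols, and cells positive for the reporter were sorted and expanded. Wild type and Tbx21-/- cells were used for RNA-seq (2 libraries per genotype), for H3K4me1 ChIP-seq and for H3K27me3 ChIP-seq (1 library per genotype each). T-bet ChIP-seq was made from 1 wild type library. Chromatin was cut with micrococcal nuclease for the histone marks and by sonication for T-bet, per the labels' protocols. Nothing in the labels says whether the duplicate RNA libraries came from separate mice. Groups were taken from the sample labels.

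The submitters' processing notes name CASAVA 1.7, Bowtie 0.12.7, MACS 1.4.1, TopHat 1.3.3, DESeq without a version and build mm9, without saying what each was used for. The 5 lists used here came as sheets of a workbook of the authors. The deposited expression lists give for each gene an FPKM value (fragments scaled to transcript length and library size) per genotype, in which the authors combined the duplicate libraries, and the authors' log2 ratio of Tbx21-/- over wild type. The values show that every listed gene changed at least 2-fold and had at least 5.02 FPKM in its higher genotype; the test behind the lists is not given in the sources used here. The log2 of the ratio of the FPKM values differed from the authors' log2 ratio by a median of 0.0262 over 429 genes and by more than 0.5 in 6, with the same direction in each; 3 genes were under 2-fold by FPKM. The deposited region lists give each region's position, its count of tags as counted by the authors' peak caller, its fold enrichment (a ratio, set by the authors' caller against its control) and the closest gene, and the T-bet list also the authors' false discovery rate in percent. The T-bet library was compared with an input library of Th1 cells, per the labels. For the histone lists the control of the caller is not given in the sources used here, and the lists lack genes active in T cells generally, such as Cd4, Cd3e, Ptprc and Lck, so they hold selected regions and not all regions of a mark. Coordinates were used as given. In 10 T-bet, 12 H3K4me1 and 6 H3K27me3 entries the gene name had turned into a date and was not matched.

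From these lists, genes were matched by symbol and synonym to the protein-coding genes of a RefSeq table (assembly GRCm38.p6, used for names only), giving a background of 21900 genes. Matches were found for 211 of 219 positive and 206 of 211 negative genes, and for 2271 of 2492 T-bet, 3765 of 4173 H3K4me1 and 2581 of 2875 H3K27me3 genes. The 15 gene lists (Th1, Th2, Th17, Tfh, Treg, cytotoxic and NK receptor, chemokine and chemokine receptor, cytokine, interferon response, naive and memory T cell, lineage transcription factor, B cell, myeloid and dendritic cell, CD8 T cell and NK cell, and erythroid and platelet) were fixed before the data were examined. So was the rule for named genes: for expression the 10 largest changes of each list and members of the gene lists, up to 30 per list; for regions the 5 strongest of each list and 20 fixed genes, with Tbx21 leading. Results for some genes under this rule are not reported here. Other genes named here were chosen after their values were seen, among them Ifngr2, Foxp1, Dyrk2 and Nod1.

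Shares were given with exact Clopper-Pearson 95% intervals, which cover counting error only, and compared by two-sided Fisher's exact tests with conditional odds ratios. Medians were compared by two-sided permutation tests with 100000 resamples for peak strength and 20000 for the size of the expression change. Overlap of at least 1 bp was compared with 1000 sets in which each peak was shifted by 20 to 500 kb in a random direction. The p-values of each family were adjusted after Benjamini and Hochberg at a threshold of 0.05. Genes are not independent replicates, so these tests describe the lists and not the variation between cultures. A comparison of histone signal between libraries had been planned as a log2 ratio per gene; since the lists hold selected regions with 1 tag count, Fisher's tests on the presence of a region were used in its place. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 (Mantel-Haenszel odds ratios) and matplotlib 3.10.9 were used.

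The tests were run on simulated data. For lists of 40 genes set against the positive list, Fisher's test called 0.5% of 200 lists with a planted odds ratio of 1, 25% with 5 and 97% with 20. For T-bet peaks against H3K27me3 regions, the shift test called 0% of 20 sets with no planted overlap and 100% of 20 sets with 5% of peaks placed in regions. The sets with no planted overlap were made by the same kind of shift as the test uses. The planted sets had a median of 170.5 overlapping peaks, against 16 in the data. They therefore do not show whether an excess as small as that in the data would be called. Stricter folds, other backgrounds, stronger peaks or regions and other overlap rules were tried as alternatives. Tests between single libraries, tests that leave out a library and the place of peaks relative to transcripts were not run, for want of values per library and of a genome of build mm9.

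Some T-bet peaks had many tags and little enrichment, and 16 had a fold enrichment under 1. A false discovery rate over 5% was given for 18 peaks, not all of them weak. The peak at Gsx1 had a rate of 5.26% and a fold enrichment of 12.4. The peak with most tags, 3794, lay on chromosome 17 at 39979856 to 39985860 with a fold enrichment of 1.26. These peaks were kept.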

Results

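T-bet, encoded by Tbx21, is the lineage transcription factor of interferon-gamma-producing T helper 1 (Th1) cells. The series compared mouse Th1 cells with and without Tbx21 to learn which genes T-bet turns up or down and what its binding sites and the chromatin around them look like. RNA-seq was made as 2 wild type and 2 Tbx21-/- libraries. ChIP-seq for T-bet was made from 1 wild type library, and ChIP-seq for H3K4me1 and for H3K27me3 from 1 library per genotype each, giving 9 samples in 7 groups. H3K4me1 is a histone mark typical of enhancers, and H3K27me3 is a mark of repressed chromatin laid down by Polycomb complexes. The data used here are 5 lists made by the authors: 219 genes listed as positively regulated by T-bet, 211 listed as negatively regulated, 3226 T-bet peaks, 7669 H3K4me1 regions and 3949 H3K27me3 regions. Expression is given as 1 FPKM value per genotype, without the spread between the duplicate libraries, so no error or p-value can be given for a gene's change. The sequencing depth of the libraries is unknown. All coordinates are in mouse build mm9, and the gene given for a region is the closest gene named by the authors.

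Tbx21 itself was on the positively regulated list. Its transcript stood at 271 FPKM in wild type and 124 FPKM in Tbx21-/- cells, a log2 ratio of -1.11 in the authors' deposited table. Transcript therefore remained in the cells labelled as knockout, and the FPKM value does not tell which exons the reads came from.

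Many Th1 and cytotoxic genes were on the list of genes lower in Tbx21-/- cells, and a set of Th2 genes was on the list of genes higher there. Ifng, the signature Th1 cytokine, stood at 1011 FPKM in wild type and 19.5 FPKM in Tbx21-/- cells, and the chemokine receptor Cxcr3 at 26.3 and 0.357 FPKM. In the other direction, Ecm1, an extracellular matrix protein expressed by Th2 cells, went from 95.7 to 1193 FPKM, and the Th2 cytokine gene Il5 from 18.3 to 77.2 FPKM. The numbers of genes on the 2 lists were close to equal: 219 of 430 genes, or 50.9% (exact binomial 95% interval 46.1 to 55.8), were higher in wild type (two-sided exact binomial p = 0.736). The median log2 ratio of Tbx21-/- over wild type in the authors' deposited table was -1.59 for the positively regulated genes and 1.44 for the negatively regulated genes, a median fold of 3.00 and 2.71. Every listed gene differed at least 2-fold in that table, and its higher FPKM was at least 5.11 on the positive and 5.02 on the negative list.

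The 10 largest decreases in Tbx21-/- cells were at Irx3, 1700025F22Rik, Cxcr3, Col6a1, Ifng, Ms4a7, Bst1, Kcnj8, Klra5 and Sulf2. Irx3, a homeobox transcription factor, had the lowest log2 ratio in the authors' deposited table, -8.21, with 20.4 FPKM in wild type and 0.0372 in Tbx21-/- cells. The transcript 1700025F22Rik was listed at 7.59 FPKM in wild type and at 0 in Tbx21-/- cells. Sulf2, an extracellular sulfatase, went from 41.3 to 1.61 FPKM. The 10 largest increases were at Igj, Cav3, Ambn, Ccr6, Pou2af1, 2010001M09Rik, Nts, H2-Aa, Fam183b and Ecm1. Igj, the joining chain of polymeric antibodies, had the highest log2 ratio in the authors' deposited table, 9.22, and stood at 0.0506 and 48.9 FPKM. Ccr6, a chemokine receptor of Th17 cells, went from 0.0853 to 5.90 FPKM, and the B cell coactivator gene Pou2af1 from 0.194 to 8.69 FPKM. Apart from Ecm1, each of these 10 genes had less than 1 FPKM in wild type, so that its fold rests on a value near 0. The same limit holds for the 10 largest decreases apart from Ifng and Sulf2, each with less than 1 FPKM in Tbx21-/- cells.

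**Figure D1:**
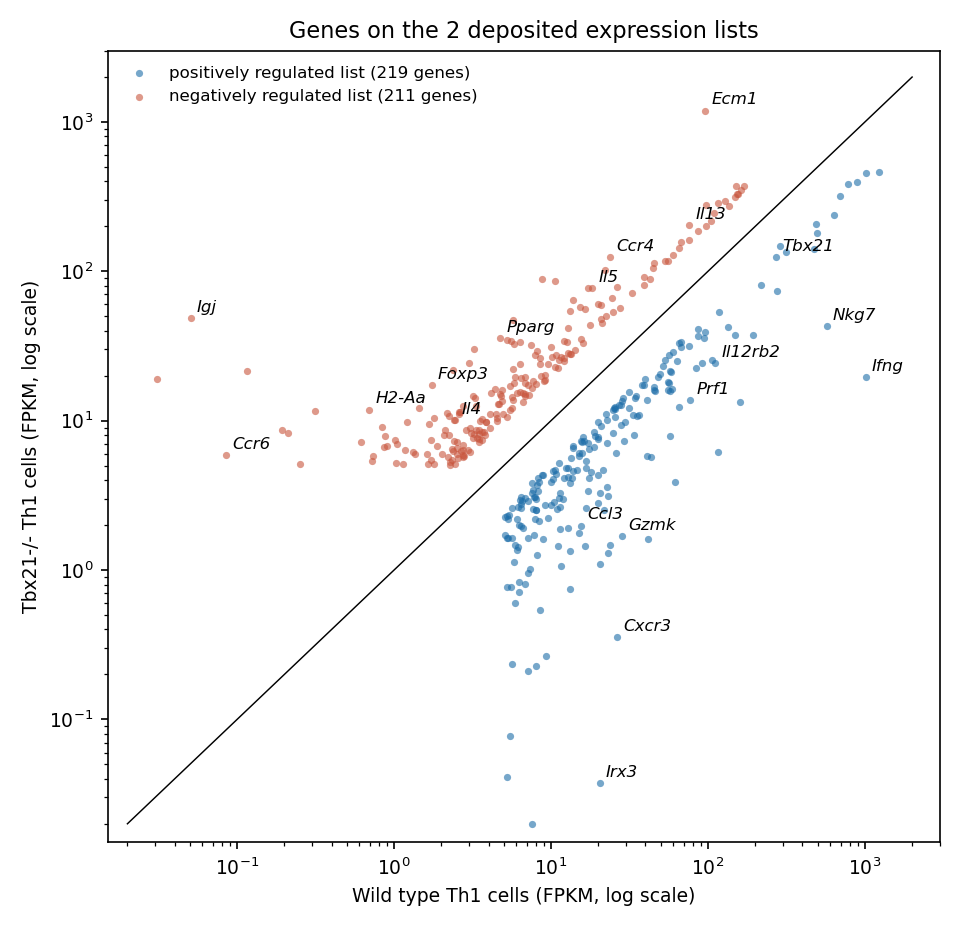
Expression of the listed genes in wild type (horizontal axis) and Tbx21-/- (vertical axis) Th1 cells, in FPKM on log scales; each point is 1 gene, blue for the 219 positively and red for the 211 negatively regulated genes, the line marks equal expression, and the gene listed at 0 is drawn at 0.02 FPKM. Ifng and Nkg7 lie far below the line at 1011 and 571 FPKM in wild type, and Ecm1 lies far above it at 1193 FPKM in Tbx21-/- cells.

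Th1 and cytotoxic genes were on the positive list more often than on the negative list. Of 40 Th1 genes fixed before the data were examined, 16 were on the positive, 2 on the negative and 22 on neither list, an odds ratio of 8.34 between the lists (Fisher's exact test, adjusted p = 0.00792 over 15 gene lists). Besides Tbx21, Ifng and Cxcr3 they were Bhlhe40, Ccl3, Ccl4, Ctsw, Furin, Havcr2, Hlx, Il12rb2, Il18r1, Il18rap, Lta, Nkg7 and Txk. Il12rb2, a subunit of the interleukin-12 receptor, went from 111 to 24.4 FPKM, and the transcription factor gene Hlx from 17.9 to 4.53 FPKM. The chemokine genes Ccl3 and Ccl4 went from 15.6 to 1.99 and from 11.1 to 1.45 FPKM. The exceptions were Serpinf1 and Tnfsf11, which were on the negative list. Of 40 cytotoxic and NK receptor genes, 19 were on the positive, 0 on the negative and 21 on neither list (Fisher's exact test, adjusted p = 3.83e-05). Markers of CD8 T cells and NK cells were on the positive list in 2 of 12 cases, Nkg7, which is also a cytotoxic gene, and Cd8a, at 39.6 FPKM in wild type and 19.1 in Tbx21-/- cells; against all coding genes their odds ratio was 20.7 (Fisher's exact test, adjusted p = 0.0109), a call lost under each of the 3 alternatives run, with odds ratios from 18.7 to 30.0 for the larger changes and 8.63 with genes of the histone lists as background (adjusted p from 0.0833 to 0.223). Whether CD8 T cells or NK cells were among the sorted cells was not tested. The cytotoxic genes included 8 granzyme genes, Prf1 for perforin, Fasl, and the receptor genes Klra5, Klrc1, Klrc2, Klrd1 and Klrk1. Nkg7, a cytotoxic granule protein, went from 571 to 42.9 FPKM, Gzmk from 28.3 to 1.69, Prf1 from 77.4 to 13.7 and Fasl from 20.1 to 2.83. The granzyme genes and the Klrc genes are families of similar sequence that can share reads, so the values of their single members are uncertain. Fisher's test counted each member as a separate gene, so the p-value of the cytotoxic and NK receptor list may be too small. Klrc1, Klrc2 and Klrc3 had log2 ratios between -3.86 and -3.84 in the authors' deposited table.

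Th2 genes were on the negative list more often than on the positive list. Of 37 Th2 genes, 12 were on the negative, 2 on the positive and 23 on neither list, an odds ratio of 0.155 for positive against negative genes (Fisher's exact test, adjusted p = 0.0299). The 12 were Areg, Ccr4, Ccr8, Cyp11a1, Ecm1, Gfi1, Il13, Il4, Il5, Kif3a, Penk and Pparg. The cytokine gene Il4 went from 2.44 to 10.1 FPKM and Il13 from 76.2 to 204 FPKM. Ccr4, a Th2 chemokine receptor, went from 23.8 to 124 FPKM, and Pparg, a nuclear receptor, from 4.76 to 35.8 FPKM. The 2 Th2 genes higher in wild type were the cytokine genes Il10 and Il24. Gata3, the lineage factor of Th2 cells, was on neither list.

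Some genes of follicular helper and regulatory T cells were on the negative list, without a difference between the lists that passed the threshold. Against all coding genes both groups were enriched among negative genes, with an odds ratio of 40.6 for follicular helper (Fisher's exact test, adjusted p = 2.54e-07) and 33.7 for regulatory T cell genes (adjusted p = 5.06e-06). Of 22 follicular helper (Tfh) genes, 6 were negative and 0 positive: Cd200, Il21, Pou2af1, Slamf6, Tcf7 and Tox2. The difference between the lists did not pass the threshold after adjustment (Fisher's exact test, p = 0.0140, adjusted p = 0.0525). Tcf7, a transcription factor of naive and memory cells, stood at 16.6 and 55.7 FPKM. Of 21 regulatory T cell (Treg) genes, 5 were negative, namely Ctla4, Ebi3, Foxp3, Izumo1r (listed as Folr4) and Penk, and 2 were positive, namely Entpd1 and Il10. Foxp3, the lineage factor of regulatory T cells, stood at 1.73 and 17.3 FPKM. The Treg split did not pass the threshold (Fisher's exact test, adjusted p = 0.525), nor did that of 24 Th17 genes, with 2 positive (Csf2, Il6st) and 3 negative (Ccr6, Il17re, Il21; adjusted p = 0.787).

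Chemokine, cytokine and transcription factor genes were on both lists. Of 37 chemokine and chemokine receptor genes 4 were positive and 6 negative, of 37 cytokine genes 6 and 9, and of 38 lineage transcription factor genes 3 and 5 (Fisher's exact test, adjusted p = 0.674 for each). Interferon response genes were positive in 6 of 47 cases (Cxcl10, Ifit1, Ifit3, Irf8, Isg15 and Usp18) and negative in 1, Iigp1 (Fisher's exact test, adjusted p = 0.305). Of 22 naive and memory T cell genes, 1 was positive and 4 were negative, namely Id3, Klf3, Slamf6 and Tcf7 (Fisher's exact test, adjusted p = 0.452). Among markers of other cell types, 5 of 36 myeloid and dendritic cell markers were on the negative and 0 on the positive list: Cd74, Cebpb, H2-Aa, H2-Ab1 and H2-Eb1 (Fisher's exact test, p = 0.0287, adjusted p = 0.0861). Against all coding genes these markers were enriched among negative genes (Fisher's exact test, odds ratio 17.4, 95% interval 5.22 to 45.7, adjusted p = 6.26e-05). Apart from Cebpb, the markers found there are genes of MHC class II presentation. Of 16 B cell markers, Blk was positive and Cd79a negative (Fisher's exact test, adjusted p = 1). Of 12 CD8 T cell and NK cell markers, Cd8a and Nkg7 were positive and 0 were negative (Fisher's exact test, adjusted p = 0.674), and 0 of 13 erythroid and platelet markers were on either list.

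**Figure D2:**
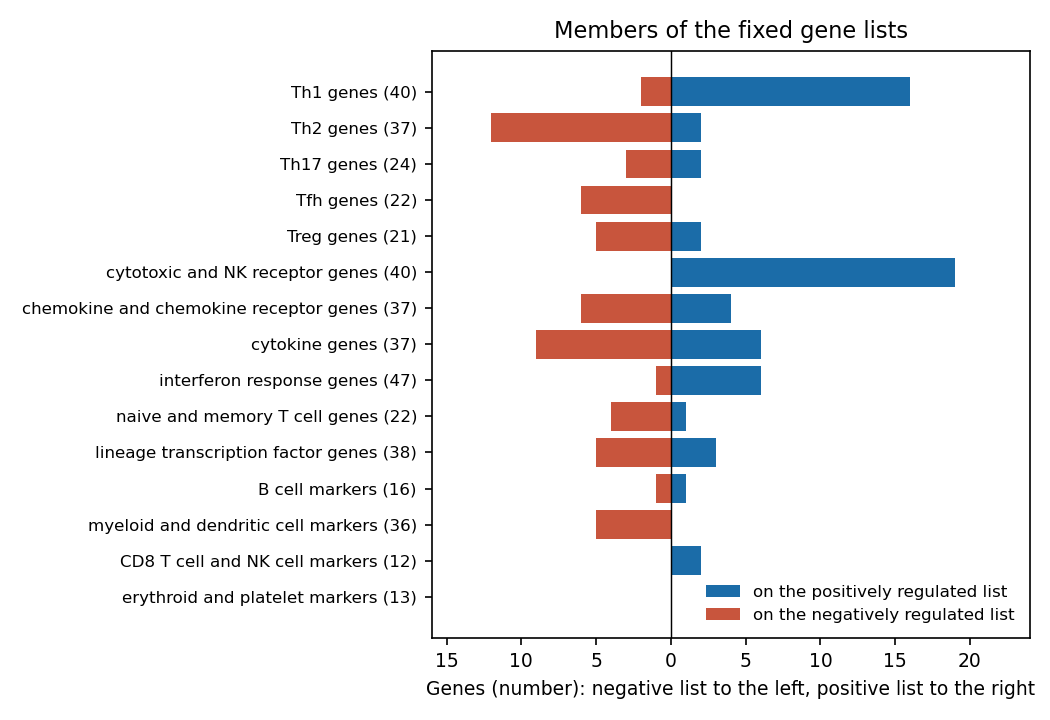
Number of members of each of the 15 fixed gene lists (size in parentheses) on the positively regulated list (blue, to the right) and on the negatively regulated list (red, to the left). Cytotoxic and NK receptor genes lie to the right with 19 against 0, and Th2 genes mainly to the left with 2 against 12.

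Against 21900 protein-coding genes as background, 9 of the 15 lists were enriched among the positive and 9 among the negative genes (Fisher's exact test, adjusted over 30 tests). The largest odds ratios were 102 for cytotoxic and NK receptor genes (95% interval 50.9 to 203) and 73.9 for Th1 genes (36.1 to 148) among positive genes, and 53.5 for Th2 genes (24.1 to 112) among negative genes. The cytotoxic and NK receptor list counts members of families that can share reads as separate genes, so its interval may be too narrow. The background also holds genes that may have been too weakly expressed to be listed. With genes near histone regions as background, which also leaves out regulated genes without such a region, the odds ratios were 20.6 for cytotoxic and NK receptor, 30.4 for Th1 and 33.7 for Th2 genes, and 3 lists were enriched among positive and 8 among negative genes. Among positive genes, Th1, cytotoxic and NK receptor, and cytokine genes kept their call under the 3 alternatives run, while Th17, Treg, chemokine and chemokine receptor, interferon response and lineage transcription factor genes and the CD8 T cell and NK cell markers lost it under at least 1. Among negative genes, Th2, Tfh, Treg, chemokine and chemokine receptor, cytokine and lineage transcription factor genes and the myeloid and dendritic cell markers kept it, while Th17 and naive and memory T cell genes lost it under at least 1.

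Genes listed as regulated lay near T-bet peaks more often than other genes, and the positively regulated genes more often than the negatively regulated genes. Of 211 positive genes matched to a protein-coding symbol, 95 were the closest gene of at least 1 T-bet peak, or 45.0% (exact 95% interval 38.2 to 52.0). Of 206 negative genes 45 were, or 21.8% (16.4 to 28.1), and of 21483 other coding genes 2131, or 9.92% (9.52 to 10.3). The odds ratio was 7.44 for positive against other genes (Fisher's exact test, 95% interval 5.59 to 9.88, adjusted p = 3.47e-38), 2.54 for negative against other genes (1.78 to 3.56, adjusted p = 8.48e-07) and 2.92 for positive against negative genes (1.87 to 4.61, adjusted p = 8.48e-07). Among the bound positive genes were Ifng, Cxcr3, Il12rb2, Ccl3, Ccl4, Prf1 and Fasl. Among the bound negative genes were Ccr6, Ccr8, Ifngr2, Il21, Gfi1 and Tcf7. The granzyme genes on the positive list had 0 peaks assigned, as did Hlx, Il4, Il5 and Il13. Every listed gene had at least 5.02 FPKM in its higher genotype, while the other coding genes also hold genes that may not be expressed. The effect of expression level on the odds ratios against other genes was not tested. With genes of the histone lists as background, the odds ratio was 3.71 for positive and 2.06 for negative against other genes. For positive against negative genes it was 1.80 (Fisher's exact test, p = 0.0275). The shares rest on the authors' assignment, and the positions of peaks relative to exons and promoters were not analysed here.

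Ifng had more T-bet peaks than any other gene in the list. Its 9 peaks lay on chromosome 10 between 117856088 and 118088610, and the strongest of them, at 117993413 to 117994025, had a fold enrichment of 5.84, the peak caller's own value as given by the authors. Cxcr3 had 1 peak, on chromosome X at 98932408 to 98932965, with a fold enrichment of 9.38. Runx3 and Stat4, which were on neither expression list, had 4 peaks each, and Gata3 had 5. Tbx21 had 1 peak, on chromosome 11 at 96992124 to 96992461, with 8 tags and a fold enrichment of 1.65. Of the 20 genes fixed for the region lists, 15 had a T-bet peak, and those without were Hlx, Il4, Il5, Il13 and Bcl6. The 5 strongest peaks were closest to Timd2, Sgip1, Hdac4, Gsx1 and Ccdc6, with fold enrichments from 17.7 at Timd2 to 12.1 at Ccdc6.

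The strongest peak of positively regulated genes was higher than that of other bound genes, and these genes had more peaks, 1.81 against 1.26 per bound gene. The median fold enrichment of a gene's strongest peak was 3.27 over 95 positive genes and 2.75 over 2131 other bound genes (two-sided permutation test, adjusted p = 0.00154). Peak by peak, the median was 2.79 over 172 peaks at positive and 2.62 over 2685 peaks at other genes, and among genes with 1 peak 2.79 and 2.63, and neither difference passed the threshold (permutation tests, p = 0.0811 and p = 0.307). Over 45 negative genes the strongest peak had a median of 2.84, and the difference of 0.09 from other bound genes did not pass the threshold (permutation test, adjusted p = 0.607). A larger change in expression at bound genes was not detected. Among positive genes the median absolute log2 ratio in the authors' deposited table was 1.54 with and 1.61 without a T-bet peak, and among negative genes it was 1.41 and 1.45 (permutation tests, adjusted p = 0.855 for both).

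Most positively regulated genes had a listed H3K4me1 region and most negatively regulated genes had none. The list holds selected regions, so a gene without one may still carry the mark. Of all 7669 regions, 711 or 9.27% were assigned to positive and 66 or 0.861% to negative genes matched to a protein-coding symbol. Listed genes without such a match, such as 0610040F04Rik with 9 regions, are not counted. Most regions lay near genes on neither list. The list of these regions comes from the wild type and Tbx21-/- libraries together, and the sources used here do not state which genotype had more signal, so a region's direction is not known. Of 211 positive genes, 148 had at least 1 region, or 70.1% (exact 95% interval 63.5 to 76.2), against 49 of 206 negative genes, or 23.8% (18.1 to 30.2), and 16.6% of other coding genes. The odds ratio was 11.8 for positive against other genes (Fisher's exact test, adjusted p = 1.46e-64) and 7.48 for positive against negative genes (95% interval 4.76 to 11.9, adjusted p = 2.56e-21). For negative against other genes it was 1.57 (Fisher's exact test, 1.11 to 2.18, adjusted p = 0.00932), a call that was lost with only the regions of more than the median number of tags (odds ratio 1.45, p = 0.0725). With genes of the other region lists as background, the odds ratio was 7.49 for positive and 0.895 for negative against other genes. Counting genes with 2 or more regions, it was 22.9 for positive against negative genes. Here too the other coding genes hold genes that may not be expressed, and the effect of this was not tested. Foxp1 had 38 regions, Ifng 35, Dyrk2 25 and Nod1 22. Some genes on neither expression list had fewer than Ifng but more than Dyrk2, such as 5031425F14Rik with 34 and Gas7 with 31. The regions of 5031425F14Rik, on chromosome 2 between 166196099 and 166390604, lay between those of the positive genes Sulf2 and Prex1. The 35 regions at Ifng lay between 117823720 and 118088814 on chromosome 10, and those of Dyrk2 began at 118092503 on the same chromosome. Among regions with more than the median number of tags, the highest fold enrichments were 38.7 at Fzd9, 31.8 at Ifng, 29.6 at Trak2, 27.2 at 1700003F12Rik and 26.9 at Tk2. Runx3 had 21 regions on chromosome 4 between 134609169 and 134752763. Cxcr3 had 7 regions, Il12rb2 4, Ccl3 4, Gata3 5 and Tbx21 1, while Hlx, Il4, Il13 and Gzmb were among the fixed genes with 0.

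A larger share of negatively than of positively regulated genes had a listed H3K27me3 region. Of all 3949 regions, 160 or 4.05% were assigned to negative genes matched to a protein-coding symbol. H3K27me3 regions were assigned to 68 of 206 negative genes, or 33.0% (exact 95% interval 26.6 to 39.9), to 34 of 211 positive genes, or 16.1% (11.4 to 21.8), and to 11.5% of other coding genes. The odds ratio was 3.78 for negative against other genes (Fisher's exact test, 95% interval 2.77 to 5.10, adjusted p = 1.18e-15) and 0.391 for positive against negative genes (0.236 to 0.637, adjusted p = 8.13e-05). For positive against other genes it was 1.47 and did not pass the threshold (Fisher's exact test, 0.986 to 2.14, adjusted p = 0.0506). It ranged from 0.746 with genes of the other region lists as background to 2.53 for genes with 2 or more regions. With 2 or more regions, the odds ratio for negative against other genes was 7.34. The other coding genes again hold genes that may not be expressed, and the effect of this was not tested. Ifngr2, the signalling subunit of the interferon-gamma receptor, had 13 regions on chromosome 16 between 91520435 and 91572233, and its transcript stood at 1.66 FPKM in wild type and 9.57 in Tbx21-/- cells. Ccr6 had 6 regions. The highest fold enrichments above the median of tags were 17.2 at Myo16, 15.4 at 3830408C21Rik, 15.1 at Rtn4rl2, and 14.1 at both Cdca7 and Il1r1. Gata3 had 3 listed regions and Il4, Bcl6 and Runx3 1 each. Ifng, Tbx21 and Cxcr3 had 0, which does not show that the mark was absent there.

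**Figure D3:**
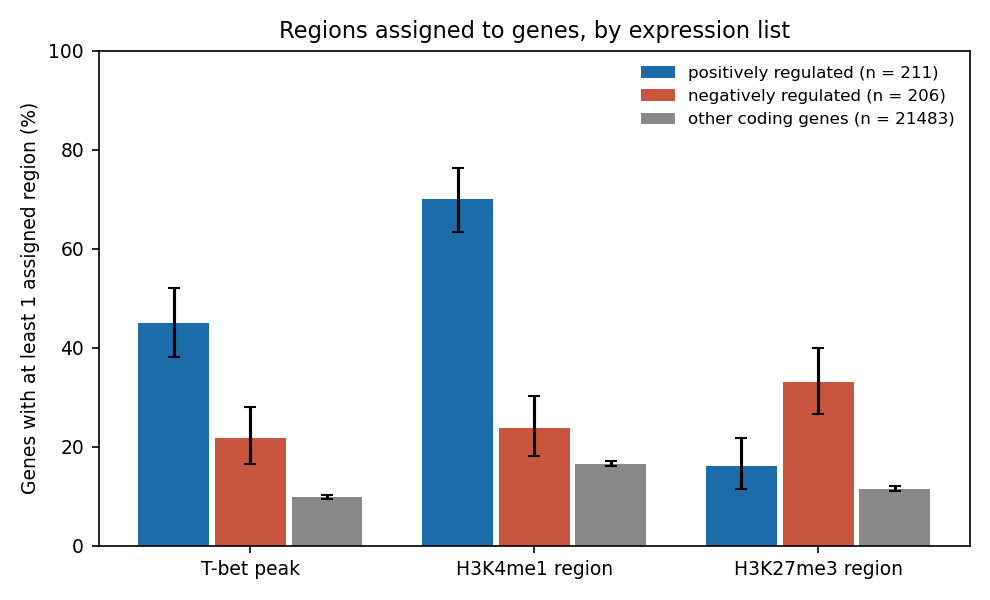
Share of genes (percent) that were the closest gene of at least 1 T-bet peak, H3K4me1 region or H3K27me3 region, for 211 positively regulated, 206 negatively regulated and 21483 other coding genes; error bars are exact 95% binomial intervals. The positive genes stand highest for T-bet (45.0%) and H3K4me1 (70.1%), the negative genes for H3K27me3 (33.0%).

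T-bet bound genes had regions of both marks more often than unbound genes, on each of the expression lists too. H3K4me1 regions were assigned to 47.3% of 2271 bound and 13.7% of 19629 unbound genes (Fisher's exact test, odds ratio 5.66, adjusted p = 6.3e-278), and H3K27me3 regions to 26.2% and 10.1% (odds ratio 3.14, adjusted p = 2.06e-89). Among positive genes, H3K4me1 regions were assigned to 83.2% of bound genes such as Ifng, Cxcr3 and Nkg7, and to 59.5% of unbound genes such as Irx3 and Il18rap (Fisher's exact test, odds ratio 3.34, adjusted p = 3.07e-04), and H3K27me3 regions to 23.2% and 10.3% (95% interval of the odds ratio 1.15 to 6.15, adjusted p = 0.0144). Among negative genes, H3K27me3 regions were assigned to 57.8% of bound genes such as Ccr6, Ifngr2, Tcf7 and Tox2, and to 26.1% of unbound genes such as Il4 and Pparg (Fisher's exact test, odds ratio 3.85, adjusted p = 1.76e-04), and H3K4me1 regions to 46.7% and 17.4% (odds ratio 4.12, adjusted p = 1.76e-04). The split of the marks between the lists was seen at unbound genes too. There H3K4me1 regions were assigned to 59.5% of positive and 17.4% of negative genes (Fisher's exact test, odds ratio 6.92, adjusted p = 1.7e-12). Genes with an H3K4me1 region had an H3K27me3 region in 25.7% of cases and other genes in 8.90% (Fisher's exact test, odds ratio 3.54, adjusted p = 1.24e-154). A gene with much sequence around it can collect regions of every kind, and gene length was not analysed here.

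In position, T-bet peaks and listed H3K4me1 regions met more often than after random shifts, but most peaks lay outside the listed regions. The list holds selected regions, so a peak outside them may still lie in chromatin with H3K4me1. Of 3226 T-bet peaks, 308 touched an H3K4me1 region, or 9.55% (exact 95% interval 8.55 to 10.6), against a mean of 28.9 when each peak was moved at random by 20 to 500 kb (permutation of peak positions, adjusted p = 0.0040, from the smallest p that 1000 shifts can give). Such peaks lay at Ifng, Cxcr3, Il12rb2, Ccl4, Nkg7 and Klrk1. At Ifng this was 1 of 9 peaks, at 118088337 to 118088610 with 6 tags, and not the strongest. Within 1 kb of an H3K4me1 region lay 524 of the 3226 peaks, 7.86 times as many as after shifting. The shifts were not limited to open chromatin or to sequence near genes. The excess therefore does not show that peaks and regions meet beyond a shared preference for such places. With H3K27me3 regions 16 peaks overlapped, against 9.93 after shifting, which did not pass the threshold (permutation of positions, adjusted p = 0.115). Of the 63 peaks at negative genes matched to a protein-coding symbol, 3 touched an H3K27me3 region, 2 of them at Ifngr2 and 1 at Ccr6. After shifting 0.283 did (permutation of positions, adjusted p = 0.00959). The 2 at Ifngr2 lay next to each other, at 91533996 to 91534518 and 91534743 to 91535190 on chromosome 16. The test moved each peak on its own and counted them as separate, so this p-value may be too small. Of the 172 peaks at positive genes matched in the same way, 0 touched an H3K27me3 region, against 0.562 after shifting. No difference from chance was detectable (permutation of positions, adjusted p = 1). Peaks of positive genes without a match, 7 at 0610040F04Rik and 1 at Mir147, were not among the 172. H3K4me1 and H3K27me3 regions touched each other in 50 of 7669 cases, against 40.8 after shifting (permutation of positions, p = 0.176).

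**Figure D4:**
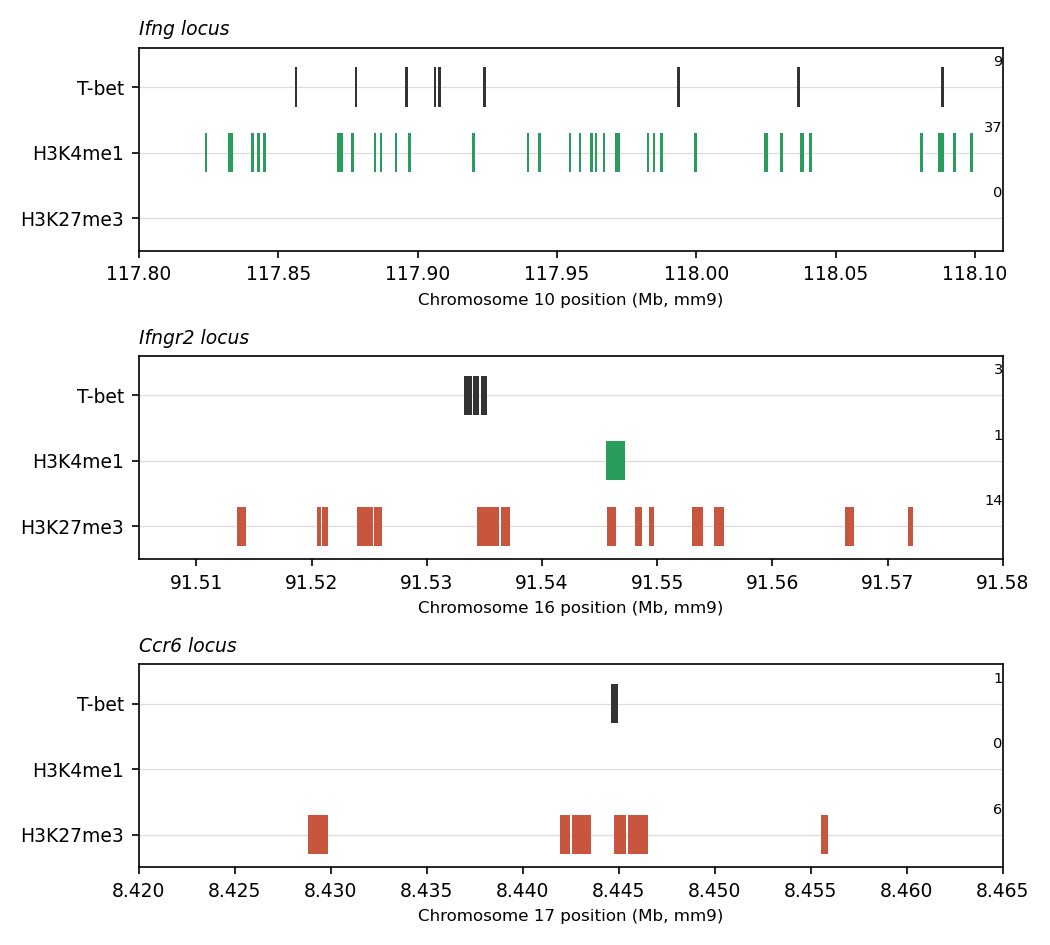
Positions of T-bet peaks and of listed H3K4me1 and H3K27me3 regions (rows) around Ifng, Ifngr2 and Ccr6, in Mb of mouse build mm9; each box is 1 region drawn to scale with a minimum width, and the number at the right counts the regions in the window. The Ifng window holds 9 T-bet peaks, 37 H3K4me1 and 0 H3K27me3 regions, and the Ccr6 window 1, 0 and 6.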

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

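Alternatives that used the ratio of FPKM values, a stricter false discovery rate, fold enrichment or number of regions per gene, the other region lists as background, the larger changes for histone regions, other overlap rules, or peak strength per peak and at genes with 1 peak were chosen after seeing the data. Of 73 alternatives for the main results, 54 kept the direction and the side of the threshold (counts stayed within 1.5 times), 5 lost the call, 4 gained one, 7 values moved and 3 odds ratios turned to the other side of 1, none of them past the threshold there. At least 4-fold, 68 positive and 59 negative genes were left, as a stricter threshold must give. Recomputed from the FPKM values with a pseudocount of 1, the median log2 ratio was -1.40 for positive and 1.27 for negative genes. A pseudocount shrinks the folds of low genes. Without a pseudocount, the log2 of the FPKM ratio differed from the authors' ratio by a median of 0.0262 over 429 genes. This is small against the change in the medians and argues against the use of FPKM values as its main source. The number of gene lists enriched among positive genes went from 9 to 3 with genes of the histone lists as background (from 9 to 8 among negative genes), and to 4 with the larger changes or with 4-fold changes, where fewer genes were tested. The odds ratio of an H3K4me1 region for negative against other genes, 1.57, lost its call in 5 settings: 1.45 with regions above the median of tags, 1.12 above the median of fold enrichment and 1.51 with the larger changes, and, in the other direction, 0.833 with 2 or more regions per gene and 0.895 with the other region lists as background. The odds ratio of an H3K27me3 region for positive against other genes, 1.47, passed the threshold at 1.75 with regions above the median of fold enrichment and at 2.53 with 2 or more regions per gene, and turned to 0.746 with the other region lists as background. The T-bet odds ratios kept their calls with genes of the histone lists as background, at 3.71 for positive against other and 1.80 for positive against negative genes. The difference in T-bet peak strength at positive genes, 0.52 for the strongest peak, lost its call at 0.17 per peak and at 0.16 for genes with 1 peak, where a gene's number of peaks cannot raise its maximum. The sum of T-bet fold enrichment over all peaks exceeded that of other bound genes by 0.67 at negative genes and passed the threshold without adjustment (permutation test, p = 0.0471). Peak by peak the median was 2.62 at both, and negative genes had 1.4 peaks per bound gene against 1.26 at other genes. T-bet peaks within 1 kb of an H3K27me3 region were 1.56 times as many as after shifting, also past the threshold. The cause was not tested for the changes in these odds ratios, sums and overlaps. Of 54 alternatives for single gene lists, 35 kept the call, 14 lost it and 5 turned to an odds ratio of 0, since no member was left: Th17, Treg and lineage transcription factor genes among positive and naive and memory T cell genes among negative genes at 4-fold, and Treg genes among positive genes with the larger changes.

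No paired analysis was possible because the expression lists hold 1 combined value per genotype and the ChIP libraries are single. For the same reason leaving out a replicate, a replicate block and count models were not run. Other scalings and pseudocounts of histone signal and means over regions were not run, because each region has 1 tag count, nor were promoter peaks or peak locations, which need gene positions in mm9. The depth of the libraries is unknown, so it cannot be said which genes or regions were too weak to be listed.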

Other observations

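Tests of explanations given here were chosen after the result was seen, except the comparison within 4 classes of wild type expression. Gene groups here were put together after their values were seen and were not tested for enrichment. H2-Aa, H2-Ab1, H2-Eb1, H2-DMa, H2-DMb1, H2-Oa and Cd74, 7 genes of MHC class II presentation on the negative list, had log2 ratios from 1.19 to 3.91 in the authors' deposited table, and 0 of them had a T-bet peak. Cd74, the invariant chain, stood at 17.3 FPKM in wild type and 77.4 in Tbx21-/- cells. The receptor genes Csf2rb and Csf2rb2, near-identical copies, went from 2.99 to 24.2 and from 2.37 to 21.7 FPKM. Among positive genes, 4 Ifitm genes, which encode interferon-induced membrane proteins, had log2 ratios from -1.88 to -1.05 in the authors' deposited table, and all 4 had an H3K4me1 region.

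H3K4me1 regions were assigned to a larger share of positive than of negative genes, and H3K27me3 regions to a smaller share. If genes with more surrounding sequence collected more regions and nothing else differed between the lists, both marks would favour the same list. The odds ratio of H3K27me3 for positive against negative genes was 0.391 (95% interval 0.236 to 0.637). H3K27me3 can differ between the lists for a reason of its own, and gene length was not analysed. Whether surrounding sequence contributes to the H3K4me1 difference is therefore not decided. Wild type expression level as the whole cause is argued against by the Mantel-Haenszel odds ratio of H3K4me1 over 4 classes of the wild type FPKM, 7.83 (4.49 to 13.6), to which the lowest class adds nothing as it held 0 positive genes. A candidate explanation is that both lists hold regions with more signal in wild type than in Tbx21-/- cells. It was drawn from the odds ratio of 7.48 for H3K4me1 and that below 1 for H3K27me3, so these values cannot test it, and it stays open, since the lists do not state the direction.

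The negative list held 15 histone H2A genes with log2 ratios from 1.01 to 1.32 in the authors' deposited table. Reads shared between these near-identical copies could give them like ratios, but the test was not decisive. Their SD of 0.0915 was below that of all 10000 random sets from the other 196 genes of the list, yet at the percentile 69.05 of sets from the 77 genes with ratios up to the highest H2A ratio, and the 2-fold limit of the list narrows both. A rise of replication-dependent histone genes in general stays open as well: the count of H1, H2B, H3 and H4 genes on the negative list was 0, and genes outside the lists have no value here. Shared reads and a rise of these genes cannot be told apart.

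Igj, Pou2af1, Cd79a and 2010001M09Rik (Mzb1), genes of B and plasma cells, were on the negative list, as were the MHC class II genes. Against all coding genes the fixed myeloid and dendritic cell markers were enriched among negative genes (Fisher's exact test, odds ratio 17.4, adjusted p = 6.26e-05). The B cell markers were not (Fisher's exact test, adjusted p = 0.196). Apart from Cebpb, the myeloid and dendritic cell markers on the negative list were Cd74, H2-Aa, H2-Ab1 and H2-Eb1, all genes of MHC class II presentation. The enrichment thus rests mainly on that group and does not favour one cell type over the other. Neither list passed the threshold between positive and negative genes. B cells, or myeloid or dendritic cells, left in the Tbx21-/- cultures from the splenocytes are a candidate source. Whether sorting for the reporter removed such cells was not tested. Of the fixed B cell markers 6.25% were on the negative list, namely Cd79a at 5.36 FPKM in Tbx21-/- cells, and Blk went the other way; of the myeloid and dendritic cell markers 13.9% were, with Cd74 highest at 77.4 FPKM. Markers outside the lists have no value here, so cells of these types and a change within T cells cannot be told apart.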
